A study of Homo sapiens with 12 samples.

How the data were processed

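Poly(A) RNA sequencing libraries (TruSeq mRNA protocol, RNA by RNeasy kit) were made from hMSCs on flat or micropillar mPOC substrates in growth or osteogenic medium, 4 groups of 3 libraries. The deposited files hold raw read counts per Ensembl gene ID, 1 file per library, as whole numbers with no normalization. Per the labels, the authors' processing fields list cutadapt 1.13, STAR, HTSeq 0.6 and DESeq2 and the genome build hg19, without the annotation release, the strand setting or any filter. Because the strand setting is not given, counts of genes that overlap on opposite strands are uncertain. Counts of near-identical paralogs and of genes with pseudogenes are uncertain for another reason, since such genes may share reads. Library totals ran from 18039644 to 31018765 counts and detected genes from 15161 to 18163. Intervals and floors given for counts cover counting error only.

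Groups were taken from the sample titles. Of 35700 gene IDs, 24558 were named from a table of IDs and symbols and another 77 from GENCODE 29, and 11065 had no symbol (0.42% to 0.515% of counts). No ID was named by guess, and no coordinates are given because the labels' genome build differs from that of the reference at hand. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 14756 (399 without a symbol), and TMM factors were applied. A quasi-likelihood model with robust estimation of the spread (glmQLFit and glmQLFTest) was fitted to all 12 libraries with 4 group means and 8 residual degrees of freedom, at a common biological coefficient of variation of 0.123. No replicate block was used, since replicate numbers did not pair the libraries. Of 18 same-numbered pairs across groups, 0 had a residual correlation over 0.1, and 3 of 12 libraries were closest on average to those of their own number. In the surface comparisons 55.3% and 52.8% of the genes passed, while TMM assumes that most do not change on balance. The median log2 fold change over all genes was 0.007 and 0.015 there. TMM factors themselves centre the fold changes near 0, so these medians do not test that assumption.

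The 5 comparisons were pillar against flat in each medium, osteogenic against growth medium on each surface, and the interaction of surface and medium. Genes pass at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. The p-values measure the spread between libraries of 1 experiment. Log2 fold changes carry an approximate standard error (SE), worked back from the test. It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Levels are CPM, read counts scaled to the normalized library total, with SD over 3 libraries. An exact permutation test of 3 against 3 cannot go below 0.1, so none is given per gene. Where a group held 0 counts, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact 95% interval. The likeness of effects is given as correlations across genes without p.

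Before the data were examined, 33 gene lists were fixed: osteoblast, chondrocyte and adipocyte genes, collagens, matrix glycoproteins and proteoglycans, matrix remodelling, YAP and TAZ targets, actin and contractile genes, integrins, the nuclear envelope, chromatin modifiers, the cell cycle, glucocorticoid response, inflammatory genes, secreted growth factors, IGF-binding proteins, hypoxia and glycolysis, endoplasmic reticulum stress and amino acid response, cholesterol synthesis, p53, interferon, Wnt, TGF-beta and BMP targets, mechanosensitive signalling, immediate-early genes, stromal, endothelial, haematopoietic, epithelial and neural markers, mitochondrially encoded genes, ribosomal proteins and oxidative phosphorylation. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and also with an estimated correlation and with fry, which left 32 lists. Counts of members that rose or fell use the adjustment over all genes, and the count adjusted over the list alone is given where it differs.

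The genes named were chosen by a rule also fixed before the data were examined. It took the 8 highest and 8 lowest log2 fold changes per comparison (5 and 5 for the interaction) among genes that passed, with a symbol, an average log2 CPM of at least 1 and, for pairwise comparisons, no overlap between the libraries. It added up to 4 members per described list by smallest p, the reference genes RUNX2, ALPL, COL1A1, LMNA, CCN2 and ANKRD1, and up to 6 genes each way that passed alike in both surface comparisons. Of the list members the rule allows, those named were picked after their values were seen. HMOX1, TXNRD1, CTSD, GPNMB, PER3 and DBP fall outside the rule and were chosen after their values were seen. In the files the reference genes are ENSG00000124813 (RUNX2), ENSG00000162551 (ALPL), ENSG00000108821 (COL1A1), ENSG00000160789 (LMNA), ENSG00000118523 (CCN2) and ENSG00000148677 (ANKRD1). Genes linked to a person's sex and loci named after clones were left out, and some other genes that the rule picked are not named.

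The steps were tested on simulated data of 14756 genes, 200 of them changed, and a further list of genes was shifted by 1.5-fold. In the growth medium surface comparison 52.2%, 67.2% and 90.9% of genes changed by 1.5-, 2- and 4-fold were recovered, and in the interaction 23.9%, 62.7% and 77.3%. Among genes with an average log2 CPM of at least 1, 100% and 96.0% were recovered at 4-fold. Of the calls, 5.49% and 7.44% were false, and of the 32 lists left unshifted, 0 and 1 passed camera. Each simulated gene was drawn independently and few were changed, unlike in the data. These rates therefore do not cover lists whose genes move together, or a change in most genes. The recovery required at 4-fold had first been set at 80% and was lowered to 70% after the interaction gave 77.3%. Alternatives tried were RLE and upper quartile factors, no filter and a stricter filter (CPM of at least 1 in 3 libraries), DESeq2 1.42.0, limma voom, fits of only the groups compared, a replicate block with TMM or RLE factors, a fold change of at least 1.5, and leaving out each library or each replicate number. Thinning to the smallest library, offsets for GC content and transcript length (known for 97.3% of tested genes), list counts without pillar osteogenic replicate 2, and the correlation of the medium effect were added after the data were seen. The offsets also took out each library's mean deviation in log2 CPM, so they recentred the libraries too.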

Results

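The series measured poly(A) RNA of human mesenchymal stromal cells (hMSCs), multipotent cells that can form bone, cartilage and fat. The cells, at passage 4, were seeded on flat sheets or on micropillars of mPOC, a citrate-based polymer, and kept in growth medium or in osteogenic induction medium from 1 day after seeding. The labels give day 1 as the time point, without saying whether it counts from seeding or from induction. Each of the 4 groups (flat or pillar surface, growth or osteogenic medium) held 3 libraries with biological replicate numbers, 12 libraries in all, and the labels do not say whether these came from separate donors or cultures. Deposited read counts summed to 18039644 to 31018765 per library over 35700 gene IDs. Of these, 14756 passed the filter on low counts and were tested. Fibronectin (FN1) was the gene with the most counts in each library, with 2.94% to 6.50% of the total. All 13 listed mitochondrially encoded protein genes stand at 0 in every library, so that list could not be tested. The labels do not say whether such reads were removed before deposit, so the 0 does not show that these genes were silent.

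Surface and medium separated the libraries. The first principal component held 52.3% of the variance and parted the pillar libraries (45.8 to 69.0) from the flat ones (-61.9 to -55.5). The second held 20.5% and parted growth medium (27.4 to 45.0) from osteogenic medium (-62.7 to -24.6). Replicate 2 of the pillar osteogenic group stood apart on the third component (7.67% of variance), at 44.55 against -8.64 and -2.76 for the other 2 libraries of its group, and had the fewest detected genes, 15161. The labels name no sequencing run or batch, and replicate numbers did not pair libraries across groups (residual correlations of -0.061 to 0.0853 over 18 same-numbered pairs).

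**Figure D1:**
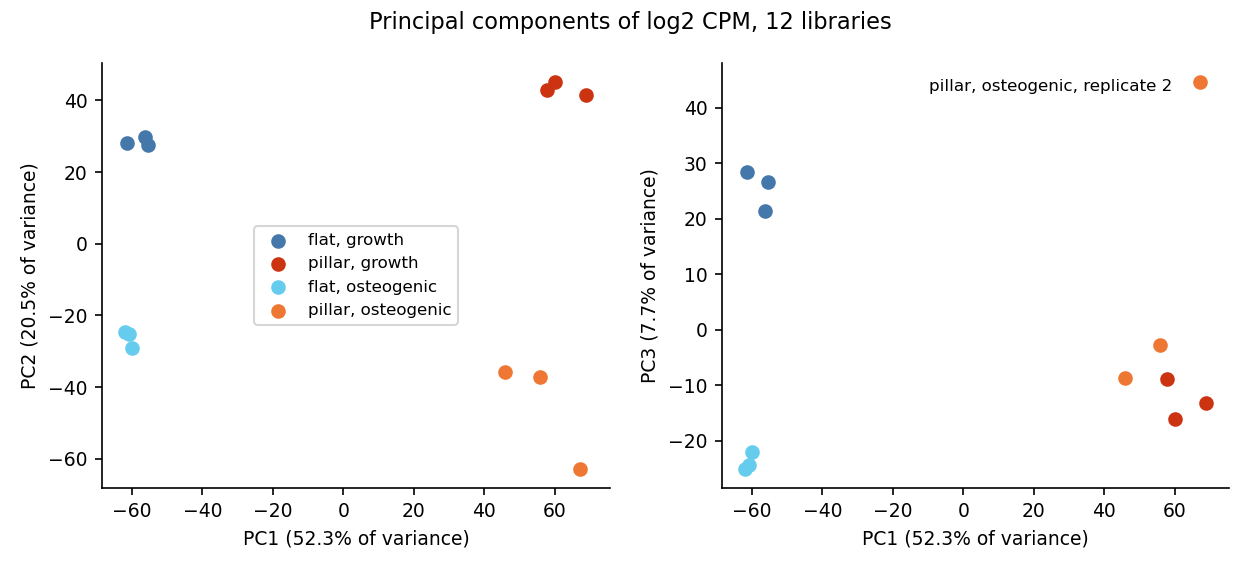
Principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM (read counts scaled to the library total), each point 1 of 12 libraries, coloured by surface and medium. The pillar libraries sit at 45.8 or above on the first component and the flat ones at -55.5 or below; pillar osteogenic replicate 2 sits at 44.55 on the third.

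The series design text names the comparison of flat and micropillar surfaces, and its title links the pillars to constriction of the nucleus. In growth medium, cells on pillars had far lower levels of genes of cell division and higher levels of endoplasmic reticulum stress and amino acid response genes than cells on flat sheets. MMP1, the collagenase that cleaves fibrillar collagen, stood at 276 ± 27.7 CPM on pillars and 3.09 ± 0.794 CPM on flat sheets (mean ± SD, n = 3), a log2 fold change of 6.47 ± 0.16 (SE) with adjusted p = 3.66e-18. The proliferation marker MKI67 stood at 1.65 ± 0.493 and 147 ± 2.49 CPM, a log2 fold change of -6.43 ± 0.45 (adjusted p = 1.56e-06). In total 8161 genes passed, 4122 higher and 4039 lower on pillars, 2974 of them by at least 2-fold. In 9231 genes (62.6%) the libraries of both surfaces did not overlap, where chance gives 10%.

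The genes with the highest log2 fold changes, all 3 pillar libraries above all 3 flat ones, included HSPA6 (10.47 ± 0.99), an inducible HSP70 chaperone, ARC (7.14 ± 0.52), an activity-induced immediate-early gene, and GADD45G (6.88 ± 0.41), a growth arrest gene. The actin-binding XIRP1 (6.49 ± 0.70) and RGS16 (6.26 ± 0.35), a regulator of G protein signalling, were among them as well. ATP6V0D2, a subunit of the vesicular proton pump, had 0 counts on flat sheets and 13.3 ± 1.31 CPM on pillars, at least 295-fold higher against a floor of 3 counts over the group. The transcription factor POU3F1 had 3 counts on flat sheets in all, a ratio of 158 with a 95% counting interval of 53.7 to 767. All 3 were in flat growth replicate 1, and against the other 2 flat libraries, at 0 counts, it was at least 105-fold higher by the same floor. HSPA6 rests on 6 counts on flat sheets, and without flat growth replicate 3 on 1, a ratio of 6200 with a 95% counting interval of 1110 to 245000. Without that library the log2 fold change of XIRP1 was 5.89. The lowest included the kinetochore genes SPC24 (-5.71 ± 0.40) and SPC25 (-5.19 ± 0.56), the mitotic spindle gene CKAP2L (-5.67 ± 0.22), the spindle checkpoint kinase BUB1B (-5.14 ± 0.55), the cell cycle repressor E2F8 (-5.06 ± 0.37), the receptor kinase KIT (-5.05 ± 0.40) and KRTAP1-1 (-5.14 ± 0.90), a keratin-associated protein with close paralogs. Without pillar growth replicate 2 SPC24 was at -6.60, and without pillar growth replicate 3 SPC25 was at -5.89. Of the genes with a log2 fold change in this paragraph, KRTAP1-1 had the highest adjusted p, 0.00102.

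Cell division fell as a group in growth medium: of the cell cycle list, 0 of 30 measured members rose and 29 fell (camera adjusted p = 2.63e-33, adjusted p = 0.0319 with an estimated correlation), with TPX2 (-3.10 ± 0.13), a spindle assembly factor, PLK1 (-3.78 ± 0.16), a mitotic kinase, and IQGAP3 (-5.005 ± 0.19), the last outside the list. Of the actin and contractile list, 1 of 31 measured members rose and 30 fell (camera adjusted p = 5.33e-26, adjusted p = 0.00416 with an estimated correlation), among them CNN2 (-2.37 ± 0.098) and ACTB (-1.89 ± 0.083). The targets of YAP and TAZ, the mechanically regulated coactivators, had 4 of 22 higher and 16 lower (camera adjusted p = 1.02e-05, adjusted p = 0.0345 with an estimated correlation). CCN2, a matricellular target, stood at -1.62 ± 0.12, ANKRD1 at -1.69 ± 0.17 and the receptor kinase AXL at -1.44 ± 0.095, all 3 lower, while coagulation factor F3 (4.29 ± 0.29) was higher. Of the nuclear envelope list, 4 of 20 measured members rose and 8 fell (4 and 9 adjusted over the list alone) (camera adjusted p = 0.0122, but adjusted p = 0.118 with an estimated correlation). Its median log2 fold change was -0.155, smaller than those of the members named next. Lamin A/C (LMNA) fell from 1162 ± 69.9 to 617 ± 13.1 CPM (log2 fold change -0.91 ± 0.076, adjusted p = 8.77e-10), and lamin B1, LMNB1 (-3.97 ± 0.22), and the lamina-associated TMPO (-1.51 ± 0.14) fell too. Mechanosensitive channels and their signalling had 4 of 25 higher and 12 lower, with CAV1 (-1.60 ± 0.11), the caveolar coat protein, lower (camera adjusted p = 0.0277, adjusted p = 0.298 with an estimated correlation).

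Matrix lists moved down on pillars in growth medium by camera, in calls that were lost with an estimated correlation. Of the collagens, 2 of 27 measured members rose and 21 fell, with COL3A1 (-2.56 ± 0.12) and COL14A1 (-2.63 ± 0.14). COL1A1, the main bone and skin collagen, stood at 3266 ± 476 CPM on pillars and 20380 ± 2440 on flat sheets (log2 fold change -2.64 ± 0.17, adjusted p = 1.12e-09). Of the matrix glycoproteins and proteoglycans, 0 of 35 measured members rose and 30 fell, including tenascin C, TNC (-2.05 ± 0.14), and elastin, ELN (-1.21 ± 0.092). Matrix remodelling and crosslinking genes were mixed. There 5 of 34 measured members rose and 23 fell (5 and 24 adjusted over the list alone), with the aggrecanase ADAMTS5 (-2.96 ± 0.12) and the crosslinking enzyme LOXL2 (-1.33 ± 0.077) lower beside the higher MMP1. Camera gave adjusted p = 7.49e-11, 9.91e-09 and 0.00146 for these 3 lists. With an estimated correlation the adjusted p was 0.11, 0.106 and 0.142, and the calls were lost. Of cholesterol synthesis genes, 0 of 24 measured members rose and 19 fell, with LSS (-1.91 ± 0.11) and mevalonate kinase, MVK (-1.84 ± 0.13) (camera adjusted p = 1.18e-06, adjusted p = 0.0968 with an estimated correlation). Of the stromal markers, 2 of 19 measured members rose and 12 fell (3 and 12 adjusted over the list alone), with endoglin, ENG (-1.35 ± 0.097), and PDGFRA (-1.61 ± 0.13) lower and the nerve growth factor receptor NGFR (4.47 ± 0.33) higher (camera adjusted p = 0.00537, adjusted p = 0.136 with an estimated correlation). Without flat growth replicate 2 NGFR was at 5.38.

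Of the stress lists that moved up by camera in growth medium, that of the endoplasmic reticulum alone kept its call with an estimated correlation. Of the list of endoplasmic reticulum stress and amino acid response genes, 24 of 26 measured members rose and 0 fell (camera adjusted p = 1.55e-43, adjusted p = 0.00416 with an estimated correlation). Its members SLC7A11 (5.41 ± 0.14) and SLC3A2 (4.16 ± 0.11) form the cystine transporter, CHAC1 (4.29 ± 0.13) degrades glutathione and HSPA5 (2.69 ± 0.098) is the reticulum's HSP70. Of the immediate-early and stress list, 18 of 22 measured members rose and 2 fell, with NR4A1 (3.50 ± 0.14) and EGR1 (3.28 ± 0.14) (camera adjusted p = 1.46e-13, adjusted p = 0.052 with an estimated correlation). Inflammatory cytokines and chemokines had 13 of 22 higher and 7 lower. Prostaglandin synthase, PTGS2 (4.99 ± 0.14), and SOD2 (2.64 ± 0.088), the mitochondrial superoxide dismutase, were higher and the chemokine CCL2 (-2.77 ± 0.18) was lower. Of the p53 list, 12 of 22 measured members rose and 6 fell, with GDF15 (4.05 ± 0.14) and SESN2 (3.21 ± 0.16), which other stress pathways also induce. Of the glucocorticoid response list, 11 of 20 measured members rose and 4 fell (12 and 4 adjusted over the list alone), with SGK1 (2.24 ± 0.11) and PER1 (1.89 ± 0.11). Camera gave adjusted p = 0.00193, 0.00193 and 0.000218 for these 3 lists, and all 3 calls were lost with an estimated correlation (adjusted p = 0.107, 0.106 and 0.106).

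Bone genes moved both ways in growth medium. Of the osteoblast list, 5 of 21 measured members rose and 5 fell (5 and 4 adjusted over the list alone). Camera did not pass the list (adjusted p = 0.317). Fry, which does not compare it with other genes, did (adjusted p = 3e-04), at a median log2 fold change of 0.065. Osteopontin, SPP1 (3.83 ± 0.11), and BMP6 (2.80 ± 0.16), a bone morphogenetic protein, rose, and RUNX2, the master regulator of osteoblasts, fell from 24.4 ± 1.42 to 12.8 ± 1.34 CPM (log2 fold change -0.92 ± 0.12, adjusted p = 1.71e-06). ALPL, alkaline phosphatase, was low at 0.880 ± 0.218 and 1.18 ± 0.0401 CPM and did not pass (log2 fold change -0.43 ± 0.47, adjusted p = 0.466). Chondrocyte genes had 2 of 15 higher and 7 lower, and adipocyte genes 4 of 14 higher and 1 lower (0 adjusted over the list alone), and camera passed neither (adjusted p = 0.183 and 0.663). Markers of other cell types were read as well. Of the epithelial keratins and related markers, 1 of 7 measured members rose and 5 fell (camera adjusted p = 0.000717, adjusted p = 0.0345 with an estimated correlation), with KRT7 (-2.87 ± 0.095) and KRT19 (-2.49 ± 0.24). The haematopoietic list had 4 of 7 higher (5 adjusted over the list alone), the endothelial list 2 of 6 higher and 2 lower, and the neural list 2 of 7 higher and 3 lower. None of these last 3 lists passed camera (adjusted p = 0.308, 0.776 and 0.441).

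The remaining 10 lists did not pass camera in growth medium (adjusted p = 0.161 to 0.77). Members higher and lower on pillars were 6 and 13 of 24 for integrins and focal adhesions, 8 and 12 of 29 for chromatin modifiers, and 12 and 17 of 36 for secreted growth factors. They were 1 and 5 of 10 for IGF-binding proteins, 6 and 7 of 23 for hypoxia and glycolysis, and 6 and 8 of 21 for Wnt targets. For these 6 lists the counts adjusted over the list alone were the same. The other 4 were the interferon response with 7 and 8 of 26 (7 and 9 adjusted over the list alone), TGF-beta and BMP targets with 8 and 9 of 21 (9 and 9), ribosomal proteins with 6 and 0 of 30 (4 and 0) and oxidative phosphorylation with 0 and 8 of 25 (0 and 7). In all 16 of 32 lists passed camera in growth medium, 5 up and 11 down, and 5 of the calls were kept with an estimated correlation. Fry, which asks whether a list's genes move one way on balance without comparing them with other genes, passed 26. Median and mean differed in sign for the adipocyte list (-0.17 and 0.46), hypoxia (-0.14 and 0.22) and Wnt targets (-0.41 and 0.12). For TGF-beta and BMP targets (0.096 and 0.24) and the endothelial list (0.47 and 0.48) both were positive while camera pointed down.

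**Figure D2:**
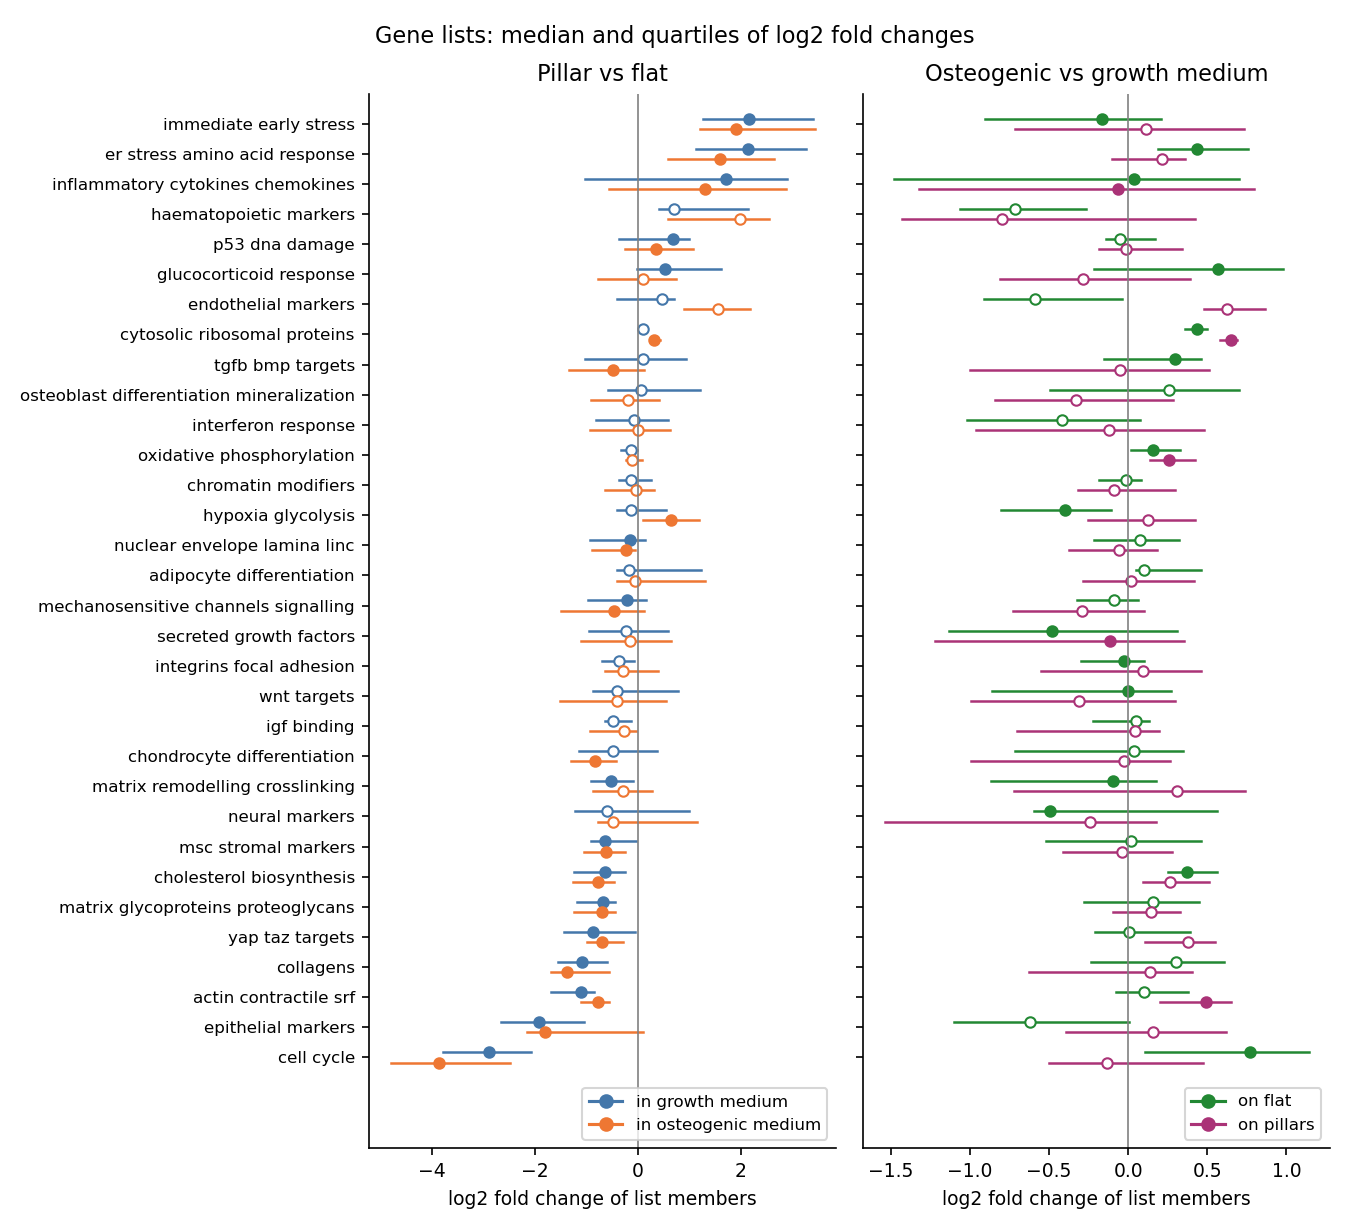
Median (points) and quartiles (lines) of the log2 fold changes of each gene list's measured members, for pillar against flat (left) and osteogenic against growth medium (right); filled points passed camera, open ones did not. The cell cycle list has the lowest median in growth medium, -2.89, and the immediate-early list the highest, 2.15.

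In osteogenic medium the surface comparison asks the same of cells under induction. Cell division and contractile genes were again lower on pillars, and endoplasmic reticulum stress and immediate-early genes were higher. MMP1 stood at 280 ± 35.6 CPM on pillars and 0.576 ± 0.188 CPM on flat sheets (n = 3 each), a log2 fold change of 8.94 ± 0.19 (adjusted p = 4.14e-19). MKI67 stood at 3.63 ± 2.94 and 218 ± 21.5 CPM (log2 fold change -5.88 ± 0.41, adjusted p = 1.72e-06). In total 7791 genes passed, 3966 higher and 3825 lower on pillars, 2757 by at least 2-fold, and 8798 genes (59.6%) had no overlap between the libraries of both surfaces (10% by chance).

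Next to MMP1 the highest log2 fold changes were those of HSPA6 (10.48 ± 0.87), ATP6V0D2 (8.72 ± 0.28), ARC (6.33 ± 0.53), XIRP1 (6.27 ± 0.68), the small GTPase RRAD (6.20 ± 0.51), NGFR (6.17 ± 0.30) and RGS16 (6.15 ± 0.39), each higher in all 3 pillar libraries. Next to MKI67 the lowest were those of DLGAP5 (-5.84 ± 0.27), KIF18B (-5.80 ± 0.26), ASPM (-5.77 ± 0.29), KNL1 (-5.65 ± 0.23), DEPDC1 (-5.59 ± 0.29) and KIF20A (-5.56 ± 0.15), all genes of mitosis, and of NEURL1B (-5.70 ± 0.39), a ubiquitin ligase of Notch signalling. SPC24 (-5.54 ± 0.37), SPC25 (-5.004 ± 0.52), CKAP2L (-5.42 ± 0.20), BUB1B (-5.17 ± 0.52) and IQGAP3 (-5.40 ± 0.17) were lower in both media. XIRP1 had the highest adjusted p of the genes named here, 1.52e-05. Some effects were larger when 1 library was left out. Without pillar osteogenic replicate 1 the log2 fold changes were -6.83 for MKI67, -6.37 for ASPM, and -7.19 for BUB1B, and SPC25 was left with 2 counts on pillars, a flat to pillar ratio of 219 (95% counting interval 60.4 to 1810). Without flat osteogenic replicate 3 ATP6V0D2 was left with 3 counts on flat sheets, a ratio of 945 (95% counting interval 323 to 4580). Without flat osteogenic replicate 1 RGS16 was left with 3 as well, a ratio of 129 (43.9 to 627), and without pillar osteogenic replicate 2 NEURL1B was at -6.41.

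By list in osteogenic medium, 30 of 30 cell cycle genes fell (camera adjusted p = 2.44e-50, adjusted p = 0.0141 with an estimated correlation), for example CENPF (-5.14 ± 0.15). The list of actin and contractile genes had 29 of 31 lower (camera adjusted p = 6.06e-14, adjusted p = 0.025 with an estimated correlation), with CALD1 (-1.53 ± 0.083) and ACTA2 (-1.71 ± 0.11). Of the nuclear envelope list, 1 of 20 measured members rose and 10 fell (2 and 10 adjusted over the list alone), at a median of -0.23 (camera adjusted p = 0.000235, adjusted p = 0.0435 with an estimated correlation). There LMNB1 (-4.66 ± 0.22) and the linker protein SYNE2 (-2.94 ± 0.18) fell, and LMNA went from 1375 ± 25.2 to 764 ± 40.4 CPM (log2 fold change -0.85 ± 0.076, adjusted p = 2.94e-09). Cholesterol synthesis had 21 of 24 lower (camera adjusted p = 5.42e-09, adjusted p = 0.0435 with an estimated correlation). Of the endoplasmic reticulum stress and amino acid list, 25 of 26 measured members rose and 1 fell (camera adjusted p = 7.17e-30, adjusted p = 0.0143 with an estimated correlation), with HERPUD1 (2.41 ± 0.094) and HSPA5 (2.49 ± 0.097). Of the immediate-early list, 20 of 22 measured members rose and 2 fell (camera adjusted p = 3.04e-15, adjusted p = 0.0435 with an estimated correlation), with ATF3 (5.65 ± 0.22) and EGR1 (3.45 ± 0.14). These 6 were the calls kept with an estimated correlation.

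The other 12 calls in osteogenic medium were lost with an estimated correlation. Collagens fell (22 of 27, 23 adjusted over the list alone, and 1 rose), with COL8A1 (-2.14 ± 0.091), COL3A1 (-2.43 ± 0.11) and COL1A1 (-2.30 ± 0.16). Matrix glycoproteins and proteoglycans had 31 of 35 lower, with decorin, DCN (-1.15 ± 0.071), and periostin, POSTN (-1.33 ± 0.095). YAP and TAZ targets had 4 of 22 higher and 17 lower, with TGFB2 (-1.57 ± 0.11), CRIM1 (-1.29 ± 0.095), CCN2 (-1.50 ± 0.12) and ANKRD1 (-0.74 ± 0.16) among the lower ones. Of TGF-beta and BMP targets, 4 of 21 measured members rose and 12 fell, with the repressor TGIF1 (1.94 ± 0.093) higher and ATOH8 (-2.87 ± 0.13) lower. Adjusted p by camera was 1.82e-12, 4.41e-10, 0.000501 and 0.00699 for these 4 lists, and adjusted p = 0.077, 0.0708, 0.0563 and 0.212 with an estimated correlation. Mechanosensitive channels and signalling had 5 higher and 15 lower (16 adjusted over the list alone), with KCNK2 (-2.95 ± 0.16), a stretch-gated potassium channel. Chondrocyte genes had 2 of 15 higher and 8 lower, with HAPLN1 (-1.41 ± 0.10) and COMP (-1.34 ± 0.11). Stromal markers had 3 of 19 higher and 13 lower (14 adjusted over the list alone), with TWIST1 (-1.83 ± 0.12). Epithelial markers had 1 of 7 higher and 4 lower, with KRT7 (-2.60 ± 0.094) and KRT19 (-2.20 ± 0.22). For these 4, camera adjusted p was 0.00765, 0.0221, 0.0121 and 0.00776, and adjusted p = 0.192, 0.192, 0.195 and 0.0612 with an estimated correlation. The other marker lists did not pass camera (adjusted p = 0.125, 0.235 and 0.749). The haematopoietic list had 5 of 7 higher and 0 lower (5 and 1 adjusted over the list alone, and 3 and 0 without pillar osteogenic replicate 2), at a median of 1.99. The endothelial list had 4 of 6 higher and 1 lower, at a median of 1.55, and the neural list 2 of 7 higher and 2 lower (2 and 3 adjusted over the list alone). Fry passed the first 2 (adjusted p = 1.48e-05 and 7.09e-06) and not the neural list (adjusted p = 0.109).

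The lists that rose without keeping their call were inflammatory genes, the p53 list, hypoxia and glycolysis, and ribosomal proteins. Inflammatory genes had 15 of 22 higher and 6 lower, with PTGS2 (3.35 ± 0.14) and CXCL8 (3.60 ± 0.31) higher and CXCL12 (-1.43 ± 0.089) lower. The p53 list had 12 of 22 higher (13 adjusted over the list alone) and 6 lower, with GDF15 (6.11 ± 0.15) and the death receptor TNFRSF10B (1.47 ± 0.088). Hypoxia and glycolysis genes had 16 of 23 higher and 4 lower, with NDRG1 (2.07 ± 0.10) and hexokinase 2, HK2 (1.63 ± 0.12). Ribosomal proteins had 26 of 30 higher (27 adjusted over the list alone, and 21 without pillar osteogenic replicate 2), with RPS14 (0.53 ± 0.089) and RPL11 (0.51 ± 0.086), whose reads pseudogenes may share. Camera adjusted p was 0.011, 0.000242, 0.000524 and 0.0056, and adjusted p = 0.192, 0.0612, 0.077 and 0.644 with an estimated correlation. The osteoblast list did not pass camera (adjusted p = 0.736) but passed fry (adjusted p = 0.0307). There 4 of 21 measured members rose and 7 fell, with SPP1 (4.003 ± 0.11) higher and osteoprotegerin, TNFRSF11B (-2.36 ± 0.17), lower. Matrix remodelling did not pass either (camera adjusted p = 0.458), at a median of -0.30 and a mean of 0.23. Of it, 7 of 34 measured members rose and 18 fell (10 and 19 adjusted over the list alone), with MMP3 (5.31 ± 0.20) higher and the crosslinking enzyme LOX (-1.44 ± 0.088) lower. RUNX2 (log2 fold change -0.28 ± 0.12, adjusted p = 0.0546) and ALPL (0.04 ± 0.45, adjusted p = 0.95) did not pass. RUNX2 passed with DESeq2 (adjusted p = 0.0358), voom (0.0419), RLE size factors (0.0484) or upper quartile factors (0.0236). It also passed without flat osteogenic replicate 3 (0.0415), pillar osteogenic replicate 1 (0.042) or pillar growth replicate 1 (0.0492). ALPL was at -0.0071 with upper quartile factors, at -0.12 and -0.18 without flat osteogenic replicates 1 and 3, and at -0.35 without pillar osteogenic replicate 2.

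Across the 14756 tested genes the surface effects in both media had a Pearson correlation of 0.752 and a Spearman correlation of 0.692, over genes, which are not independent replicates. The comparisons share no library. Genes higher on pillars in both media numbered 2620, where independent calls would give 1108, and genes lower in both numbered 2571, against 1047. Another 283 passed in opposite directions, against 2154, so that 94.8% of the genes that passed in both media had the same direction. HSPA6, ATP6V0D2, MMP1, ARC, XIRP1 and RGS16 were the 6 genes higher in both with the largest effect in the medium where it was smaller, and MKI67, SPC24, CKAP2L, BUB1B, IQGAP3 and SPC25 the 6 lower in both.

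**Figure D3:**
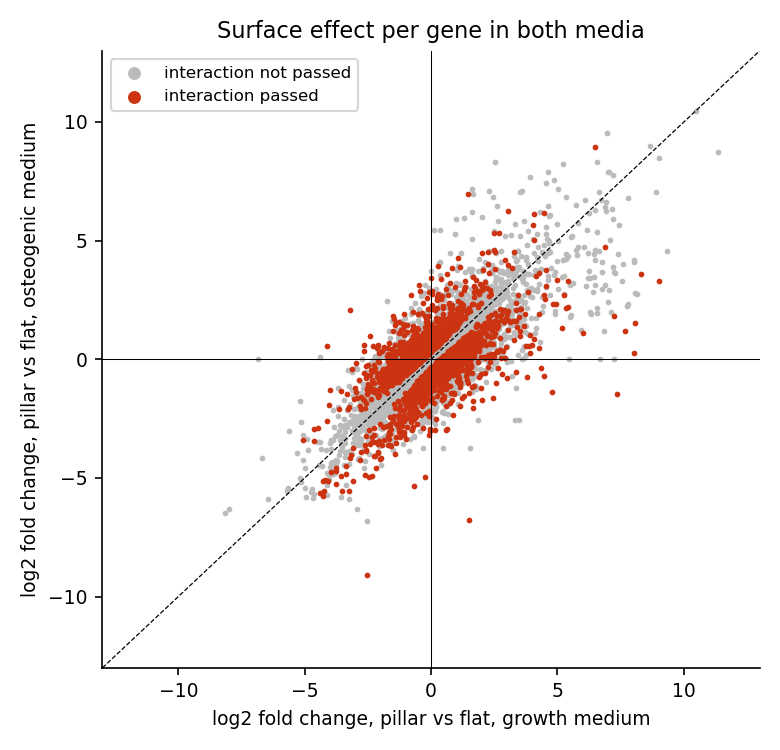
Log2 fold change of each tested gene for pillar against flat in growth medium (horizontal) and in osteogenic medium (vertical), red where the test of the difference between media passed, grey where it did not. Most genes lie along the dashed line of equal effects (Pearson 0.752 over genes), and the red ones number 3476.

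On flat sheets the comparison of media asks what the induction medium did on the control surface. The glucocorticoid-induced chaperone FKBP5 rose from 9.41 ± 1.82 to 65.01 ± 6.11 CPM (n = 3 each, log2 fold change 2.79 ± 0.15, adjusted p = 3.44e-12), and neurofilament NEFM fell from 190 ± 5.74 to 4.77 ± 0.852 CPM (log2 fold change -5.31 ± 0.16, adjusted p = 1.7e-16). By camera, ribosomal protein, amino acid response, cell cycle and cholesterol lists moved up and the hypoxia and glycolysis list moved down, but no list call on flat sheets was kept with an estimated correlation (adjusted p = 0.104 to 0.321 for these 5). In total 4085 genes passed, 2224 higher and 1861 lower in osteogenic medium, and 6598 genes had no overlap (10% by chance). The balance was the reverse among the 881 that passed by at least 2-fold, with 282 higher and 599 lower, and with upper quartile factors, with 1886 higher and 2169 lower. With offsets for GC content and transcript length 60.4% were higher, against 54.4%. These offsets also recentre each library, so this shift cannot be put down to GC content or length alone. Without replicate 3 of every group 2388 genes passed.

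Among the highest were SLC7A11 (3.04 ± 0.13), CPM (2.45 ± 0.22), a carboxypeptidase, SAPCD2 (2.35 ± 0.24), CMKLR1 (2.34 ± 0.23), the chemerin receptor, SLC43A2 (2.25 ± 0.17), an amino acid transporter, and the pseudogene NMRAL2P (2.25 ± 0.28), whose reads its parent gene may share. ATP6V0D2 had 0 counts in growth medium and 10 in osteogenic medium, at least 2.75-fold higher, and passed (adjusted p = 0.0164), but not with voom or without flat osteogenic replicate 3 (adjusted p = 0.0993). Without that library 3 counts are left, which is the floor, so no fold is given. Among the lowest were PRSS35 (-8.42 ± 0.40), a serine protease, RANBP3L (-7.25 ± 0.26), HID1 (-6.15 ± 0.58), GNA14 (-5.59 ± 0.24) and SLCO4A1 (-5.32 ± 0.32). The betaine transporter SLC6A12 fell from 728 counts to 2, a ratio of 436 with a 95% counting interval of 120 to 3610. NMRAL2P had the highest adjusted p of the genes given here with a log2 fold change, 1.82e-06.

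Of the ribosomal proteins, 27 of 30 measured members rose and 0 fell (29 and 0 adjusted over the list alone), with RPL10 (0.91 ± 0.093) and RPL3 (0.66 ± 0.074). Endoplasmic reticulum stress and amino acid genes had 18 of 26 higher (19 adjusted over the list alone) and 2 lower, with asparagine synthetase, ASNS (1.80 ± 0.092). The cell cycle list had 16 of 30 higher (18 adjusted over the list alone) and 3 lower, with KIF20A (1.35 ± 0.12) and PLK1 (1.35 ± 0.13). Glucocorticoid response genes had 10 of 20 higher and 3 lower (4 adjusted over the list alone), with PER1 (1.83 ± 0.11) higher and the kinase SGK1 (-1.50 ± 0.11) lower. Cholesterol synthesis had 16 of 24 higher, with HMGCS1 (0.85 ± 0.11). Oxidative phosphorylation had 9 of 25 higher, with NDUFV1 (0.58 ± 0.09) and UQCRC2 (0.60 ± 0.098), and TGF-beta and BMP targets 10 of 21 higher and 2 lower (11 and 3 adjusted over the list alone), with LMCD1 (1.66 ± 0.14) and ID3 (0.57 ± 0.11). Camera adjusted p for these 7 lists ran from 1.64e-11 for ribosomal proteins to 0.0329 for oxidative phosphorylation. With an estimated correlation the adjusted p was 0.252, 0.147, 0.321, 0.147, 0.147, 0.544 and 0.414 in the order given, so none of these calls was kept.

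Of hypoxia and glycolysis genes, 1 of 23 measured members rose and 15 fell, with PFKFB3 (-1.99 ± 0.12), a driver of glycolysis, and VEGFA (-1.08 ± 0.098). Secreted growth factors had 8 of 36 higher and 17 lower (9 and 20 adjusted over the list alone), with neuregulin, NRG1 (-1.63 ± 0.093), and BDNF (-1.31 ± 0.10) lower and the BMP antagonist GREM1 (1.82 ± 0.11) higher. Matrix remodelling had 6 of 34 higher and 12 lower (14 adjusted over the list alone), with LOXL4 (-3.93 ± 0.13) and TIMP3 (-2.35 ± 0.099). Immediate-early genes had 3 of 22 higher and 9 lower, with IER3 (-2.71 ± 0.094) and JUN (-1.20 ± 0.088). Inflammatory genes had 4 of 22 higher and 6 lower (5 and 7 adjusted over the list alone), with CCL2 (-3.93 ± 0.19) and CSF1 (-2.78 ± 0.12). Their median was 0.036 (-0.0042 with upper quartile factors) and their mean -0.11, and camera pointed down. Of integrins, 7 of 24 fell and 1 rose, with ITGA8 (-2.42 ± 0.15) and ITGA2 (-2.41 ± 0.14). Wnt targets had 4 of 21 higher and 6 lower (7 adjusted over the list alone), with the Wnt inhibitors NOTUM (-4.16 ± 0.23) and SFRP1 (-1.44 ± 0.15). The neural list had 2 of 7 higher, with TUBB3 (0.94 ± 0.13), and 2 lower, NEFM among them. Camera adjusted p for these 8 lists ran from 2.91e-07 for hypoxia and glycolysis to 0.0329 for Wnt targets. With an estimated correlation the adjusted p was 0.104, 0.147, 0.147, 0.462, 0.234, 0.564, 0.462 and 0.147 in the order given, and no call was kept. Fry passed 22 lists.

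The osteoblast list did not pass camera on flat sheets (adjusted p = 0.489) but passed fry (adjusted p = 0.0304). Of it, 4 of 21 measured members rose and 5 fell (6 and 5 adjusted over the list alone), with BMP6 (1.35 ± 0.16) and osteonectin, SPARC (0.42 ± 0.075), higher. RUNX2 (0.047 ± 0.12, adjusted p = 0.82) and ALPL (0.20 ± 0.46, adjusted p = 0.797) did not pass, and without flat osteogenic replicate 2 they stood at -0.0095 and -0.27. COL1A1 (0.64 ± 0.16, adjusted p = 0.00642) and ANKRD1 (1.76 ± 0.17, adjusted p = 1.52e-06) rose. So did CCN2 (0.40 ± 0.12, adjusted p = 0.0129) and LMNA (0.24 ± 0.075, adjusted p = 0.0183), but CCN2 did not pass without flat growth replicate 3 (adjusted p = 0.0508). LMNA did not pass without flat growth replicate 1 (0.0655), flat growth replicate 3 (0.0884) or flat osteogenic replicate 2 (0.0701).

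On pillars the same change of medium moved more genes past the threshold, 6349 against 4085 on flat sheets. In fits of only the groups compared the gap was smaller, with 5757 on pillars against 4852 on flat sheets. The secretory chaperone SCG5 rose from 1.73 ± 0.602 to 17.3 ± 0.475 CPM (n = 3 each, log2 fold change 3.32 ± 0.28, adjusted p = 4.88e-09) and the protease PRSS35 fell from 440 ± 86.6 to 2.37 ± 1.56 CPM (log2 fold change -7.49 ± 0.38, adjusted p = 2.05e-07). By camera, ribosomal protein, contractile and oxidative phosphorylation lists moved up, but no list call on pillars was kept with an estimated correlation (adjusted p = 0.378 to 0.594 for these 3). In total 6349 genes passed, 3396 higher and 2953 lower in osteogenic medium, and 7500 had no overlap (10% by chance). The balance was the reverse among the 1459 that passed by at least 2-fold, with 465 higher and 994 lower. Of all genes that passed, 53.5% were higher, and 65.0% with offsets for GC content and transcript length, which also recentre each library.

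Higher in all 3 osteogenic libraries on pillars were ANKRD30B (3.62 ± 0.56), ANKRD1 (2.71 ± 0.17), the growth factor epigen, EPGN (2.53 ± 0.17), the microtubule protein MAP2 (2.41 ± 0.36), ZNF365 (2.40 ± 0.21) and the keratin-associated KRTAP2-3 (2.46 ± 0.48), which has a near-identical paralog. KRTAP1-1 (3.22 ± 0.97, adjusted p = 0.0253) rests on single libraries. It stood at 1.65 without pillar osteogenic replicate 1 and did not pass without pillar growth replicate 1 (adjusted p = 0.0584), 2 (0.087) or 3 (0.0722). Lower were GNA14 (-7.63 ± 0.34), C2CD4B (-7.08 ± 0.72), RANBP3L (-6.87 ± 0.29), SLC6A12 (-6.03 ± 0.25), SLCO4A1 (-4.96 ± 0.23), the Wnt target CCN4 (-4.86 ± 0.31) and the interferon-induced OAS1 (-4.73 ± 0.43). KRTAP2-3 had the highest adjusted p of these apart from KRTAP1-1, 0.00171. Without pillar growth replicate 2 ANKRD30B was at 4.37, and without pillar growth replicate 3 KRTAP2-3 was at 3.04. Without pillar osteogenic replicate 1 GNA14 was left with 2 counts in osteogenic medium, a growth to osteogenic ratio of 465 (95% counting interval 128 to 3840). Without pillar osteogenic replicate 3 C2CD4B was left with 1, a ratio of 370 (66.2 to 14700), and PRSS35 was at -8.23.

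All 30 ribosomal protein genes rose, with RPL4 (0.75 ± 0.076) and RPS18 (0.74 ± 0.079) (camera adjusted p = 5.6e-15, adjusted p = 0.49 with an estimated correlation). Of the actin and contractile list, 20 of 31 measured members rose and 3 fell (22 and 3 adjusted over the list alone), with ACTG1 (1.38 ± 0.088) and CNN2 (1.16 ± 0.095) (camera adjusted p = 1.89e-07, adjusted p = 0.378 with an estimated correlation). Oxidative phosphorylation had 15 of 25 higher and 0 lower (1 adjusted over the list alone), with NDUFV1 (1.05 ± 0.093) and UQCRC2 (0.72 ± 0.099). Inflammatory genes had 5 of 22 higher and 9 lower, with SOD2 (-2.34 ± 0.086) and PTGS2 (-3.29 ± 0.13). Secreted growth factors had 9 of 36 higher (11 adjusted over the list alone) and 15 lower, with TGFB2 (-2.60 ± 0.11) and TGFB3 (-2.77 ± 0.17) lower and GDF15 (1.73 ± 0.12) higher. Camera adjusted p was 0.00921, 0.0028 and 0.0239 for these 3, and adjusted p = 0.594, 0.435 and 0.49 with an estimated correlation. Glucocorticoid response genes did not pass camera (adjusted p = 0.219). Of them, 5 of 20 measured members rose and 9 fell (6 and 10 adjusted over the list alone), with FKBP5 (2.18 ± 0.15) higher and NFKBIA (-2.84 ± 0.13) and SGK1 (-2.16 ± 0.11) lower. Fry passed 23 lists against 5 by camera.

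Of the osteoblast list on pillars, 3 of 21 measured members rose and 7 fell (camera adjusted p = 0.219, fry adjusted p = 0.000486), with BMP6 (-2.05 ± 0.15) and TNFRSF11B (-1.74 ± 0.16) lower. RUNX2 rose from 12.8 ± 1.34 to 20.7 ± 1.55 CPM (log2 fold change 0.68 ± 0.12, adjusted p = 0.000137). COL1A1 (0.98 ± 0.16), LMNA (0.31 ± 0.075) and CCN2 (0.51 ± 0.12) rose (adjusted p = 0.000113, 0.00204 and 0.00115), and ALPL did not pass (0.66 ± 0.47, adjusted p = 0.267). Across genes the medium effect on flat sheets and on pillars had a Pearson correlation of 0.462 and a Spearman correlation of 0.368. Of the genes that passed on both surfaces, 85.6% had the same direction, and 348 had opposite directions where independent calls would give 873.

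**Figure D4:**
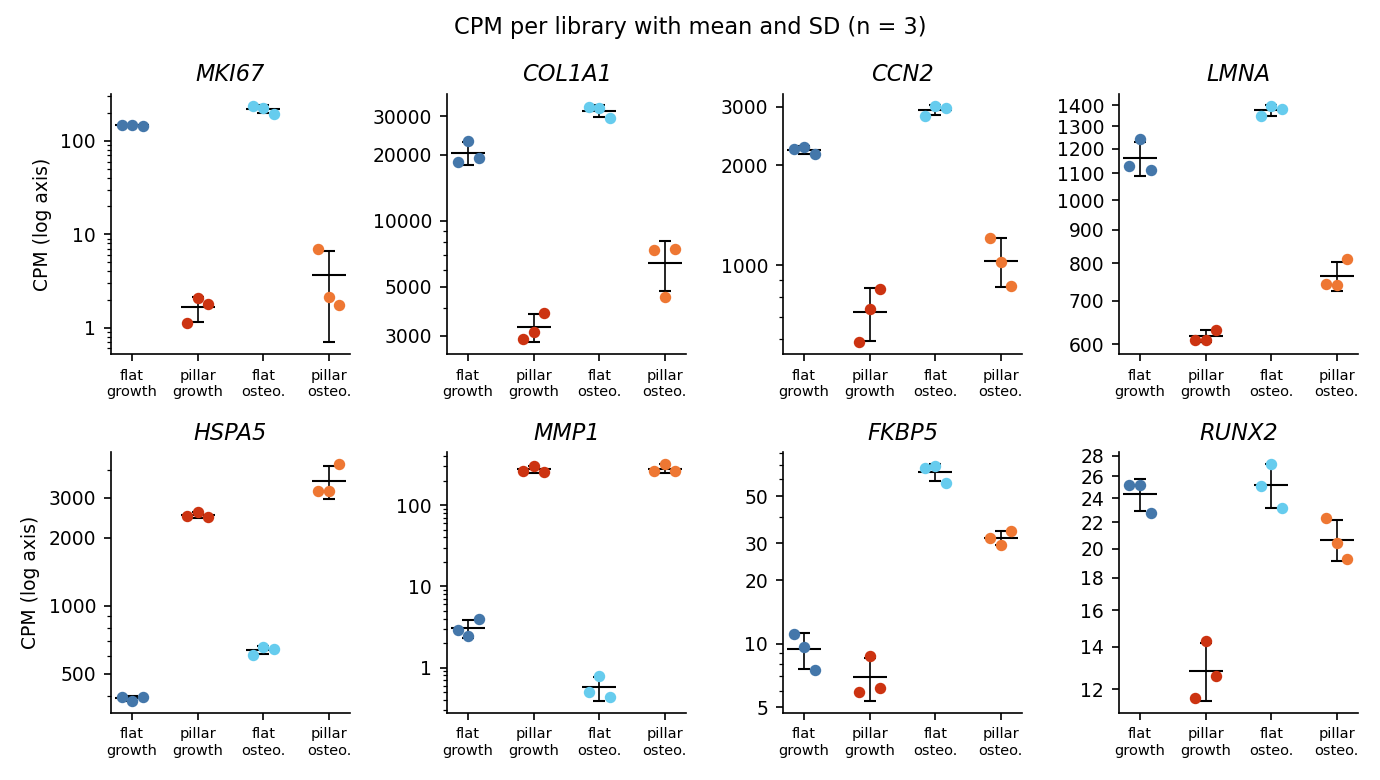
CPM on a log axis for 8 genes, each point 1 library (n = 3 per group), with horizontal bars at the mean and error bars of 1 SD. MKI67 and COL1A1 are lower on pillars in both media, MMP1 and HSPA5 higher, and FKBP5 is higher in osteogenic medium on both surfaces.

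The interaction tests whether the surface effect differs between media; a positive value means a higher pillar to flat ratio in osteogenic medium. BMP6 was higher on pillars in growth medium (83.01 ± 17.0 against 11.9 ± 1.48 CPM on flat sheets) and lower on pillars in osteogenic medium (20.01 ± 2.90 against 30.5 ± 4.68 CPM, n = 3 each), a difference of -3.41 ± 0.22 on the log2 scale (adjusted p = 5.81e-10). NEFM was lower on pillars in growth medium (66.6 ± 3.38 against 190 ± 5.74 CPM) and higher in osteogenic medium (17.2 ± 4.40 against 4.77 ± 0.852 CPM), a difference of 3.34 ± 0.20 (adjusted p = 1.84e-10). Glucocorticoid response genes had lower, and hypoxia and glycolysis genes higher, pillar to flat ratios in osteogenic medium. In total 3476 genes passed, 1842 positive and 1634 negative, while of the 931 that passed by at least 2-fold 372 were positive and 559 negative. Without replicate 2 of every group 1776 passed, and without replicate 3 of every group 1866. Of the genes that passed, 63.0% were positive with offsets for GC content and transcript length, against 1842 of 3476 without them. The offsets also recentre each library.

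Values for genes here are the interaction and, after it, the log2 fold change for pillar against flat from growth to osteogenic medium. Among the highest were NEFM (3.34 ± 0.20, from -1.51 to 1.83), parathyroid hormone-like hormone, PTHLH (3.30 ± 0.34, from -0.42 to 2.88), and CDCP1 (3.01 ± 0.25, from -1.09 to 1.92), and next to BMP6 the lowest were ephrin B2, EFNB2 (-3.92 ± 0.43, from 3.38 to -0.55), F3 (-3.82 ± 0.39, from 4.29 to 0.47), NRGN (-3.69 ± 0.61, from 1.65 to -2.05) and FAM43A (-3.57 ± 0.30, from 0.62 to -2.95). Their adjusted p was at most 0.000138, that of NRGN. Without flat osteogenic replicate 3 PTHLH was at 3.89. Of the glucocorticoid list, 2 of 20 were positive and 12 negative (14 adjusted over the list alone), with KLF9 (-1.97 ± 0.16, from 0.12 to -1.85), NFKBIA (-2.06 ± 0.17, from 1.37 to -0.69), PER1 (-1.47 ± 0.14, from 1.89 to 0.43) and TSC22D3 (-1.29 ± 0.13, from 0.61 to -0.68) (camera adjusted p = 1.5e-09, adjusted p = 0.0398 with an estimated correlation). Of hypoxia and glycolysis genes, 15 of 23 were positive (16 adjusted over the list alone), with ENO2 (1.40 ± 0.13, from -0.21 to 1.19), HK2 (1.77 ± 0.17, from -0.15 to 1.63) and the glucose transporter SLC2A1 (0.98 ± 0.11, from -0.92 to 0.065) (camera adjusted p = 3.47e-08, adjusted p = 0.0398 with an estimated correlation). These calls alone were kept with an estimated correlation.

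Of the other 8 lists that passed camera in the interaction, actin and contractile genes had 17 of 31 positive and 1 negative (18 and 2 adjusted over the list alone), with ACTG1 (1.15 ± 0.12, from -1.79 to -0.64) and ZYX (0.81 ± 0.11, from -1.24 to -0.43). Cell cycle genes had 3 of 30 positive and 13 negative (4 and 14 adjusted over the list alone), with KIF20A (-2.32 ± 0.21, from -3.25 to -5.56) and CENPF (-2.04 ± 0.19, from -3.10 to -5.14). Endoplasmic reticulum stress and amino acid genes had 3 of 26 positive and 11 negative (3 and 12 adjusted over the list alone), with SLC7A11 (-3.21 ± 0.17, from 5.41 to 2.20) and ASNS (-1.23 ± 0.12, from 1.96 to 0.73). Matrix remodelling had 13 of 34 positive and 5 negative (15 and 6 adjusted over the list alone), with ADAMTS5 (1.56 ± 0.16, from -2.96 to -1.40). TGF-beta and BMP targets had 1 of 21 positive and 10 negative, with ATOH8 (-2.16 ± 0.18, from -0.70 to -2.87) and ID4 (-1.57 ± 0.20, from 1.68 to 0.11). Camera adjusted p was 8.08e-06, 4.6e-06, 1.68e-05, 0.000108 and 0.000606, and adjusted p = 0.18, 0.408, 0.264, 0.18 and 0.215 with an estimated correlation. The osteoblast list had 2 of 21 positive and 6 negative, with TNFRSF11B (-1.08 ± 0.22, from -1.28 to -2.36), the endothelial list 3 of 6 positive and 1 negative, with ERG (2.71 ± 0.28, from -0.70 to 2.01) and TEK (0.89 ± 0.27, from -2.24 to -1.36), and ribosomal proteins 7 of 30 positive and 1 negative (4 and 0 without pillar osteogenic replicate 2), with RPL23 (0.56 ± 0.15, from -0.018 to 0.54) and RPL11 (0.42 ± 0.12, from 0.091 to 0.51). Camera gave these 3 adjusted p = 0.0418, and the estimated correlation adjusted p = 0.18, 0.18 and 0.802. TEK did not pass without flat growth replicate 1 (adjusted p = 0.0555), pillar growth replicate 3 (0.0571) or pillar osteogenic replicate 3 (0.0516), nor RPL11 without flat osteogenic replicate 1 (0.0588). Fry passed 14 lists.

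RUNX2 (0.64 ± 0.17, adjusted p = 0.0109) and ANKRD1 (0.95 ± 0.23, adjusted p = 0.00902) passed the interaction. The surface effect of ANKRD1 was -1.69 in growth and -0.74 in osteogenic medium, and that of RUNX2 -0.92 and -0.28, where the latter did not pass. ALPL (0.47 ± 0.66, adjusted p = 0.651), LMNA (0.066 ± 0.11, adjusted p = 0.702) and CCN2 (0.11 ± 0.16, adjusted p = 0.661) did not pass, and CCN2 stood at -0.017 without pillar growth replicate 1 and at -0.0165 without pillar osteogenic replicate 1. COL1A1 did not pass (0.34 ± 0.22, adjusted p = 0.29), but passed without pillar osteogenic replicate 2 (0.54, adjusted p = 0.00978) and with no filter on low counts (adjusted p = 0.0271).

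Median, mean and camera direction of a list did not all have the same sign for some lists beyond those given for growth medium. For the surface in osteogenic medium these were matrix remodelling, adipocyte, glucocorticoid response and neural markers. For the medium on flat sheets they were chondrocyte, inflammatory, IGF-binding proteins, Wnt targets and stromal markers, with Wnt targets at a median of 0. For the medium on pillars they were collagens, matrix remodelling, integrins focal adhesion, IGF-binding proteins, p53, immediate early stress and stromal markers, and for the interaction collagens, secreted growth factors, IGF-binding proteins, Wnt targets and haematopoietic markers. Of these, camera passed inflammatory genes and Wnt targets on flat sheets only.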

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

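The tests of depth, GC content and length, of pillar osteogenic replicate 2 and of other splits were set after the main results but before their own values were seen; those of harvest stress and of shared heat shock reads were chosen afterwards, and the standard for mixing was made stricter after its value was seen. No group is large enough to test a single library against the others of its group. What follows differed between media or between surfaces by a test of the difference itself, the interaction of surface and medium.

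In all 3476 genes passed that test. The 10 lists that passed it by camera had median log2 differences of -0.70 for glucocorticoid response, -0.60 for cell cycle, -0.39 for TGF-beta and BMP targets, -0.32 for endoplasmic reticulum stress and amino acid response and -0.27 for osteoblast genes. They were 0.61 for hypoxia and glycolysis, 1.17 for endothelial markers, 0.37 for actin and contractile genes, 0.23 for matrix remodelling and 0.20 for ribosomal proteins. Only the calls for glucocorticoid response and for hypoxia and glycolysis were kept with an estimated correlation (adjusted p = 0.0398 for both).

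Among the genes given in the text, the log2 difference of the surface effect between media was negative for EFNB2 (-3.92), F3 (-3.82), NRGN (-3.69), FAM43A (-3.57), BMP6 (-3.41), SLC7A11 (-3.21), KIF20A (-2.32), ATOH8 (-2.16), NFKBIA (-2.06), GNA14 (-2.04), CENPF (-2.04), KLF9 (-1.97) and PTGS2 (-1.64). Smaller negative differences were those of ID4 (-1.57), PER1 (-1.47), TSC22D3 (-1.29), ASNS (-1.23), TXNRD1 (-1.10), TNFRSF11B (-1.08), HMOX1 (-0.76), SGK1 (-0.67) and FKBP5 (-0.61). Positive differences were those of NEFM (3.34), PTHLH (3.30), CDCP1 (3.01), PER3 (2.85), ERG (2.71), MMP1 (2.46), DBP (2.38), GDF15 (2.06), HK2 (1.77) and NGFR (1.70). Smaller positive ones were those of ADAMTS5 (1.56), ENO2 (1.40), ACTG1 (1.15), SLC2A1 (0.98), ANKRD1 (0.95), TEK (0.89), ZYX (0.81), RUNX2 (0.64), RPL23 (0.56), NDUFV1 (0.47), RPL11 (0.42) and CTSD (0.38). That of SLC6A12 was 2.47, a fitted value that rests on a group with 2 counts. The least certain of these had adjusted p = 0.0429 (FKBP5).

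The first pattern weighed is the surface difference itself, 8161 genes in growth medium. Depth as the whole cause is argued against by 8061 genes after every library was thinned to the smallest total, and GC content and transcript length by 8333 genes with offsets for both. A stress of minutes at harvest as the whole cause is argued against by the cell cycle list, whose mRNAs last hours and whose median log2 fold change was -2.89. Surface is the factor the design names, so a response to the pillars is a hypothesis that remains open, as do differences in cell density or attachment between the surfaces, which the labels do not give.

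The second pattern is the higher heat shock and immediate-early genes on pillars. Reads shared between HSPA6 and its close relatives as the whole cause of the pattern are argued against by the other heat shock genes, whose median log2 fold change in growth medium was 0.642. That value does not show where the reads counted to HSPA6 itself came from, and some of these other genes had been seen before the test. A stress of minutes at harvest, if cells came off pillars more slowly, cannot be told apart from a stress during culture. Of the immediate-early list, 18 of 22 members were higher in growth medium, which both explanations give, and no time course or harvest control is at hand. A biological response to the surface stays open too.

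The third pattern is pillar osteogenic replicate 2, which stands apart on the third component. Lower depth is argued against by detected genes, which at 1 common total lay 1722 below the nearer of the other 2 libraries, and GC content and length by the 1.6% of the variance of its deviation that they explained. RNA mixed in from another group remains open: the highest median share of another group's level gained by genes at least 16-fold higher there was -0.347%, but for pillar growth, with 11 such genes, the 95% bound of the median reaches 4.14%. For flat growth that bound was 0.761% and for flat osteogenic -0.17%. The design gives no group to test a biological explanation.

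Other splits of the same libraries were counted for each comparison. For each pairwise comparison the real split was the 1 of 10 with the most genes, and 10 splits are too few for a share under 0.05. The real values were 8161, 7791, 4085 and 6349 genes, and the highest of the other splits gave 0, 0, 0 and 5. Each of those other splits mixes libraries of both real groups, so a real difference adds to the spread within groups. That alone keeps their counts low, so they are no baseline for chance. For the interaction the real split gave 3476 genes and was the 1 of 60 with the most, and the highest other split gave 2928. These splits exchange pillar and flat libraries within a medium, so they change the surface effect along with its difference between media. They are therefore no measure of chance for the interaction, which was left open although a share under 0.05 had been set beforehand to count against it.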

How the results depend on the processing

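Thinning, GC and length offsets and the alternatives of the medium-effect correlation were chosen after the data were seen. The number of genes passing moved by less than 1.5 times under RLE and upper quartile factors, no filter, the stricter filter, DESeq2, voom, the replicate block with TMM or RLE factors, thinning and GC and length offsets, in every comparison. Fits of only the groups compared, run for the pairwise comparisons alone, stayed within 1.5 times as well. With the block 7999, 7635, 3924, 6183 and 3272 genes passed (in the order surface in growth and osteogenic medium, medium on flat and pillars, interaction), with thinning 8061, 7553, 4003, 6215 and 3326, and with the offsets 8333, 8044, 4434, 6543 and 3223. A required fold change of at least 1.5 gave 5389, 4911, 1889, 3320 and 2288, since it removes genes by construction. The balance of higher and lower genes depended on the setting. With upper quartile factors 46.5%, 46.3%, 46.5%, 48.3% and 52.8% of the genes that passed were higher, against 50.5%, 50.9%, 54.4%, 53.5% and 1842 of 3476 as reported. With the offsets it was 46.4%, 52.1%, 60.4%, 65.0% and 63.0%, at 1.5-fold 51.9%, 50.8%, 47.5%, 44.3% and 46.5%, and for the interaction with no filter 48.2%. The offsets both correct for GC content and length and recentre each library, and which of these moved the balance was not tested. Leaving out libraries or replicate numbers gave 6740 to 8719, 6294 to 7884, 2388 to 4733, 4341 to 6431 and 1776 to 3710, the lowest without a whole replicate number, which leaves 2 libraries per group.

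Lists passing camera numbered 16, 18, 15, 5 and 10 as reported and 5, 6, 0, 0 and 2 with an estimated correlation, which was above the preset 0.01 for 26 of 32 lists in the first comparison and 27 in each other. Fry, another test, gave 26, 24, 22, 23 and 14. Without single libraries they numbered 16 to 16, 18 to 18, 14 to 16, 4 to 7 and 7 to 10. The correlation of the surface effect was 0.792 with the stricter filter, above 0.752 by more than its spread of 0.0386, and fewer noisy genes remain there by construction. Leaving out 1 library gave 0.682 to 0.721, all lower, and 0.348 to 0.425 for the medium effect against 0.462. The filter on low counts was rerun for each of these fits, so the genes covered can differ from those of the reported values. The spread of 0.0386 comes from the same fits, and why the values were lower was not tested.

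Of 258 gene results, 257 kept their direction and side of the threshold with RLE factors, 257 with DESeq2, 256 with voom, 256 with upper quartile factors, 257 without filter, 257 with the block and 258 with the stricter filter. ALPL in the osteogenic surface comparison, which did not pass, turned to -0.0071 with upper quartile factors, which lowered the median of all genes there from 0.015 to -0.037. A value so near 0 changes sign by that shift alone. RUNX2 in that comparison passed with RLE, upper quartile factors, DESeq2 and voom. ATP6V0D2 on flat sheets did not pass with voom (2.35), KRTAP1-1 on pillars did not pass with the block (3.02, and 3.00 with RLE factors), and COL1A1 passed the interaction without filter (0.33). Causes beyond such shifts were not tested. Depth limits genes near the floor, such as POU3F1 and SLC6A12.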

Other observations

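All tests in this part were chosen after some members of each list had been seen in the results, so members not yet seen were tested apart from the full lists. Genes of the oxidative response linked to the transcription factor NRF2 were higher on pillars, 24 of 25 in growth medium and 25 of 25 in osteogenic medium, and 0 fell in either. Heme oxygenase 1, HMOX1, had log2 fold changes of 4.54 ± 0.11 and 3.78 ± 0.10 and thioredoxin reductase 1, TXNRD1, 3.01 ± 0.10 and 1.91 ± 0.095 (n = 3 per group). Lysosome and proton pump genes were higher as well, 24 and 27 of 30, with cathepsin D, CTSD (0.67 ± 0.094 and 1.04 ± 0.094), and the lysosomal glycoprotein GPNMB (0.90 ± 0.094 and 1.24 ± 0.094). Of the heat shock list, 18 and 17 of 20 rose on pillars and 1 fell in each medium. Of 16 clock genes, 9 rose on pillars in growth medium and 14 in osteogenic medium, with 2 and 1 lower. Clock genes fell on flat sheets in osteogenic medium, 13 of 16 against 1 that rose, with PER3 (-2.58 ± 0.17) and DBP (-2.97 ± 0.24). In the interaction 9 clock genes were positive and 3 negative, with PER3 at 2.85 ± 0.23 (surface effect -1.27 in growth and 1.58 in osteogenic medium) and DBP at 2.38 ± 0.33 (-0.95 and 1.43). The highest adjusted p of a value given here for a gene was 0.00072, that of DBP for the surface in growth medium.

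One hypothesis is that the NRF2-linked list as a whole is higher on pillars. Of 19 members not yet seen, 18 rose in growth medium and 19 in osteogenic medium, with a median log2 fold change of 1.75 in growth medium (camera adjusted p = 1.59e-25, adjusted p = 0.000205 with an estimated correlation), as that hypothesis needs. For the hypothesis that lysosome genes as a whole are higher, 23 and 26 of 29 unseen members rose, with a median of 0.532 in growth medium (adjusted p = 1.09e-10, and adjusted p = 0.000736 with an estimated correlation). For heat shock genes, 12 and 11 of 14 unseen members rose, with a median of 0.513 (adjusted p = 0.0159). That call was lost with an estimated correlation (adjusted p = 0.359 in growth medium and 0.107 in osteogenic medium). For clock genes in the interaction, the median of 13 unseen members was 0.599 (adjusted p = 0.0376, lost at adjusted p = 0.139 with an estimated correlation). The calls of these 13 within single comparisons were kept. On pillars 8 rose and 0 fell in growth medium (adjusted p = 5.6e-05, and adjusted p = 0.00495 with an estimated correlation), and 11 and 1 in osteogenic medium (adjusted p = 6.05e-08 and 0.00136). In osteogenic medium against growth medium 11 fell and 0 rose on flat sheets (adjusted p = 1.92e-09 and 0.0013), and 4 and 1 on pillars (adjusted p = 0.00315 and 0.0341). These remain hypotheses, since the lists were written after the data were seen. Levels of clock genes also vary with the time of harvest, which may have differed between groups and is not in the labels.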
